A study of Mus musculus with 8 samples.

How the data were processed

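Motor neurons derived from male mouse embryonic stem cells were profiled on 1-colour Agilent SurePrint G3 mouse gene expression arrays. The titles name an Hb9-GFP line, in which green fluorescent protein reports the motor neuron gene Mnx1 (also called Hb9). Whole embryoid bodies were split into single cells on day 5 of differentiation, after retinoic acid and Sonic hedgehog had been given from day 2, and GDNF was present from then until sampling, per the labels' protocols. Control cells and cells with a knockout of Litchi were sampled on day 7 and day 9, with 2 arrays in each of the 4 groups and 8 arrays in all. Groups, days and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

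RNA was extracted with Trizol and treated with DNase, and 0.5 ug was labelled with Cy3, per the labels' protocols, which give an RNA integrity number above 9. The scanner images were read with Agilent Feature Extraction 10.5.1, per the submitters' processing notes. Per the file headers, the processed signal is a spot intensity after background subtraction and detrending within the array, with no scaling between arrays. The authors also deposited a table of log2 values for the same arrays. Its 8 columns each had a median of 5.80, and their sorted values differed by at most 0.001 log2 units, as quantile normalization leaves them; their Pearson correlation with the log2 processed signal of the same array, across probes, was 0.998 or more. The offset that sets the baseline of that table stays unknown. It served only as an alternative.

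Each array held 62976 spots. The 3671 control spots and between 104 and 166 spots marked as outliers per array were left out, and no spot was saturated. Spots of 1 probe were averaged on the log2 scale, which left 55681 probes. The log2 processed signal minus each array's 75th percentile was the expression value. That percentile ran from 649 to 1691 intensity units, and between 55.9% and 67.9% of spots were well above background. All 4 arrays of replicate 1 were brighter than those of replicate 2. A probe was kept if it was well above background on both arrays of at least 1 group. Where a gene had several kept probes, the probe with the highest mean over all 8 arrays stood for it. Kept probes of 1 gene differed in sign past the threshold in 4 genes for the mean of both days, none of them named here, and in 0 genes for each other comparison, among 3988 genes with more than 1 kept probe.

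The planned gene name column was absent from the files, so probes were named through the RefSeq accession they carry and a table of mouse genes on the assembly GRCm38.p6. A symbol was found for 26307 of the 55681 probes (47.2%), standing for 19900 genes, and 1486 further RefSeq accessions found no match. Another 16194 probes are named only by a genome position. The array's positions are on mm9, so the table served for names, chromosome membership and the order of genes along a chromosome, and none of its coordinates is printed. After the filter, 24623 genes were tested, of which 15031 had a symbol. Litchi was found 0 times among the names and synonyms of the table, so the level of the targeted gene could not be checked against the labels. Mnx1 was not analysed here.

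Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). All 8 arrays entered 1 fit of 4 group means with 4 residual and 2.53 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The 6 contrasts were knockout against control on day 7 and on day 9, day 9 against day 7 in each genotype, the difference between the 2 knockout effects (an interaction term), and the mean of the 2 knockout effects, which sets 4 arrays against 4. Log2 changes of named genes are given ± their standard error (SE) from this fit. A gene not well above background on any array of a group has only a bound there. Its change is given as "at least N-fold": the bright group's mean against the mean, per array, of the higher of the gene's own signal and the lowest signal among probes well above background. Where 1 array of a group was below background, this is said beside the value.

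Of 41 gene lists written before the data were examined, 39 had the minimum of 5 measured members and were tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the lists within a contrast. With a correlation estimated from the residuals, none of the 39 lists passed in any contrast, and that p is given beside each list. Each list's called members are counted over all genes tested and also adjusted over the list alone.

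Genes to be named were fixed before the data were examined: Litchi, Mnx1, Isl1, Lhx3, Chat, Olig2 and Mki67; up to 10 called genes with a symbol and with the largest rise, and as many with the largest fall, that moved the same way in both replicate numbers (5 for the interaction and the mean of both days, or the 5 smallest p-values where fewer passed); and up to 4 members with the smallest p in each list described. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here. The alternatives were quantile normalization, a median shift, normexp background correction with an offset of 50, the deposited log2 values, no filter and a stricter filter on dim probes, a floor, other probe rules, the replicate number as a block, a trend in the spread with robust moderation, fits of 4 arrays, other thresholds, and leaving out each array in turn. Normexp was run on the median spot signal, since the mean signal was absent from the files.

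In simulated data, 200 of 24623 genes were changed by 2-fold or 4-fold. For knockout against control on day 7, 33% of 2-fold and 93% of 4-fold changes were called (7 false calls). For day 9, 17% and 81% were called (6 false). For day 9 against day 7 the shares were 24% and 87% in control cells (6 false) and 25% and 91% in knockout cells (8 false). They were 1% and 60% for the interaction (4 false) and 76% and 98% for the mean of both days (3 false). A list of 20 members shifted by 1 log2 unit gave an adjusted p of 1.23e-32 at the preset and 0.00715 with an estimated correlation. Here 0 unshifted lists passed, but in the real data 9 lists did for replicate 1 against 2, so false lists stay possible. The number of arrays limits precision. All 8 lay on 1 slide, scanned in 1 session, so neither differs between groups.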

Results

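RNA abundance was measured on 8 arrays of mouse embryonic stem cell derived motor neuron cultures, 2 each for control cells on day 7, Litchi knockout cells on day 7, control cells on day 9 and knockout cells on day 9. The 75th percentile of the processed signal, which stands for the brightness of an array, ran from 649 intensity units (control, day 7, replicate 2) to 1691 (knockout, day 7, replicate 1). Across genes, the 2 arrays of a group correlated at a Pearson r between 0.989 and 0.994, and arrays of different groups at r between 0.962 and 0.988. No p is given, since genes are not independent replicates. The first principal component held 45.1% of the variance and parted the days, and the second held 26.5% and parted the genotypes. The 2 arrays of control day 9 lay apart on the first component, at 11.1 (replicate 1) and 43.8 (replicate 2).

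**Figure D1:**
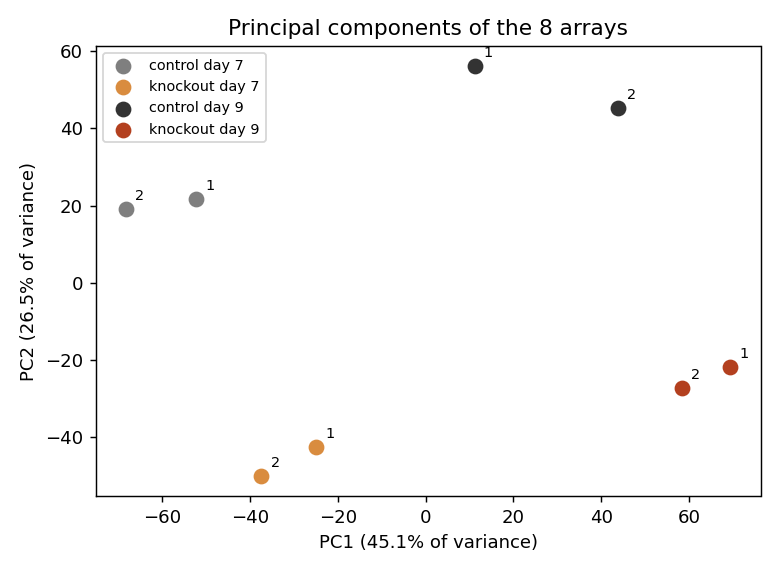
Each point is 1 of the 8 arrays, placed by its scores on the first (horizontal) and second (vertical) principal components of log2 signal over all tested genes, with colours for the 4 groups and the replicate number beside each point. The control arrays lie at 19.02 or above on the second component and the knockout arrays at -22.0 or below, and control day 9 replicate 1 lies at 11.1 on the first component, between its partner at 43.8 and the day 7 arrays.

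Knockout cells were first compared with control cells on day 7, the earlier sampling. Knockout cells held more of the imprinted noncoding RNAs Meg3 (log2 change 2.27 ± 0.22 SE, adjusted p = 0.0286) and H19 (2.00 ± 0.21, 0.0349), n = 2 arrays per group throughout. They held less of 2 imprinted genes that restrain growth, Grb10 (-3.88 ± 0.28, 0.0106), an adaptor of the insulin receptor, and Cdkn1c (-2.16 ± 0.24, 0.0389), an inhibitor of cyclin-dependent kinases. The serpin gene Serpinb9g, of a family that inhibits granzymes, was also lower (-3.40 ± 0.23, 0.0106). Interferon response genes lay above control in all 16 measured members, with a median of 2.46. Neuronal lists lay below control, the synaptic vesicle genes by a median of -0.51.

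Of 24623 genes tested, 53 passed on day 7, 24 higher and 29 lower, and 4658 had an unadjusted p under 0.05. All calls of this and the later comparisons had the same sign in both replicate numbers. The share of calls that were higher was 45.3%, against 55.6% after quantile normalization and 58.9% after a median shift, so the balance of rises and falls was not fixed. The median shift moved the median change of all genes, and the list medians with it, from -0.05 to 0.08 on day 7, from -0.02 to 0.19 on day 9 and from -0.04 to 0.13 for the mean of both days. It moved that of day 9 against day 7 in knockout cells from -0.12 to 0.04, and every change here is relative to the array's 75th percentile. Of the 53 calls, 34 had a symbol, with 8 on the X chromosome (Fisher's exact test, two-sided, adjusted p = 0.00064 over 21 chromosomes). Chromosome 13 had 6, all lower (0.0171). The split was chosen after seeing the calls, and p treats close copies as independent.

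On the X chromosome, the lymphocyte-regulated family members Xlr4b (2.10 ± 0.22), Xlr3a (1.92 ± 0.17), Xlr4a (1.90 ± 0.15) and Xlr3b (1.69 ± 0.16) rose at adjusted p between 0.0151 and 0.0349. These copies are close in sequence, so their probes can share targets, and the same holds for the Serpinb9 genes. The adhesion receptor gene Adgrd1 was at least 6.02-fold higher (adjusted p = 0.0286), with both control arrays below background. Cldn11, a tight junction gene of myelinating cells, rose by 1.88 ± 0.21 (0.0396). Rerg, a small Ras-like GTPase, rose by 1.81 ± 0.16 (0.0190) and Ccdc69, a regulator of the spindle, by 1.22 ± 0.13 (0.0349), each with 1 of 2 control arrays below background. Other serpins of the chromosome 13 cluster were lower, with Serpinb9e at -3.30 ± 0.23 and Serpinb9f at -3.29 ± 0.21 (both 0.0106). Serpinb9c was at -3.14 ± 0.36 (0.0415). The placental cathepsin Ctsr was at least 6.14-fold lower (0.0349), with both knockout arrays below background. The placental hormone gene Prl2a1 fell by 2.89 ± 0.24 (0.0176) and the X-linked reproductive homeobox gene Rhox12 by 2.83 ± 0.30 (0.0378). The gene 3830417A13Rik, named without a function, fell by 2.84 ± 0.29 (0.0349). The transmembrane protein gene Tmem125 fell by 3.05 ± 0.34 (0.0396), with 1 of 2 knockout arrays below background.

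Of 5 measured genes of the imprinted Dlk1-Dio3 cluster, 1 passed over all genes, and adjusted over the list alone 3 were higher and 2 lower (camera adjusted p = 0.211, adjusted p = 0.424 with an estimated correlation). Mirg, a noncoding RNA of that cluster, stood at 1.23 ± 0.21 (0.0811) and Dio3, which inactivates thyroid hormone, at -1.51 ± 0.34 (0.107). Of 19 other imprinted genes, 1 was higher and 2 lower over all genes, and 7 were higher and 4 lower over the list alone (camera adjusted p = 0.309, adjusted p = 0.485 with an estimated correlation). Their median was 0.27 and their mean -0.15. Zim1, an imprinted zinc finger gene, stood at -2.15 ± 0.38 (0.0854), with 1 of 2 knockout arrays below background. The 3 measured Y-linked genes, too few for the list test, had 0 calls by limma over all genes and 3 higher over the list alone, 3 also being higher at an unadjusted p under 0.05. The RNA helicase gene Ddx3y stood at 0.87 ± 0.14 (0.0747), the translation factor gene Eif2s3y at 0.86 ± 0.13 (0.0682) and the histone demethylase gene Uty at 1.11 ± 0.33 (0.163), with 1 of 2 control arrays below background for Uty.

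**Figure D2:**
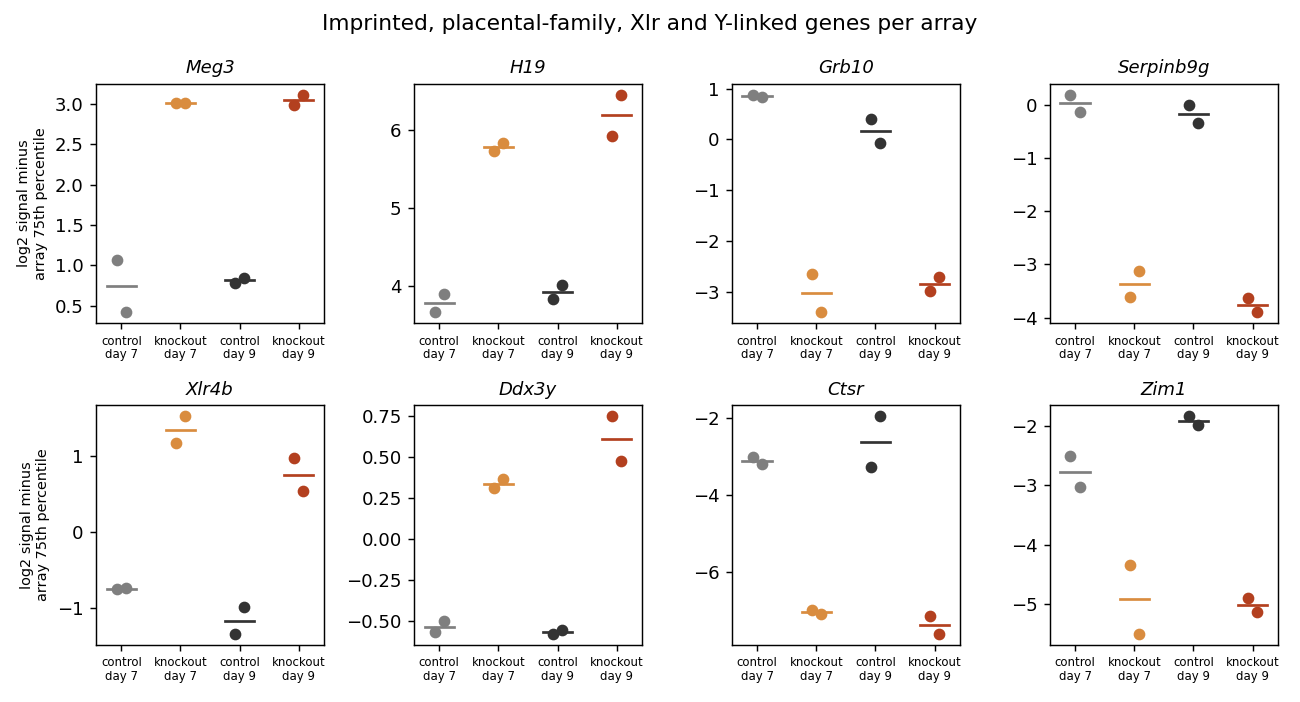
Each panel shows 1 imprinted, placental-family, Xlr or Y-linked gene, with log2 signal minus the array's 75th percentile on the vertical axis, a point per array for each of the 4 groups on the horizontal axis and a line at the group mean (n = 2). On both days Meg3 lies higher in knockout cells, by 2.27 and 2.24, and Grb10 lies lower, at -3.88 and -3.02.

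None of the 16 interferon response genes passed limma over all genes on day 7 (0 calls, 15 higher at an unadjusted p under 0.05), and 14 were higher over the list alone (camera adjusted p = 8.48e-15, adjusted p = 0.350 with an estimated correlation). The deconjugating protease gene Usp18 stood at 2.47 ± 0.33 (0.0601), the ubiquitin-like modifier gene Isg15 at 2.91 ± 0.46 (0.0738), the RNA sensor gene Ddx58 at 2.13 ± 0.33 (0.0738) and the tethering factor gene Bst2 at 2.45 ± 0.40 (0.0767). Of the interferon genes themselves, which were chosen after their values were seen, Ifna4 was at least 6.59-fold higher without passing (0.0708), and Ifnb1 stood at 2.05 ± 0.57 (0.148), with 1 of 2 control arrays below background. The list median per array, relative to each gene's mean, was -2.29 and -2.78 in control cells on day 7 and 0.22 and -0.16 in knockout cells. On day 9 it was 0.02 and 1.67 in control cells and 2.01 and 1.60 in knockout cells, so the arrays of control day 9 differed by 1.65.

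**Figure D3:**
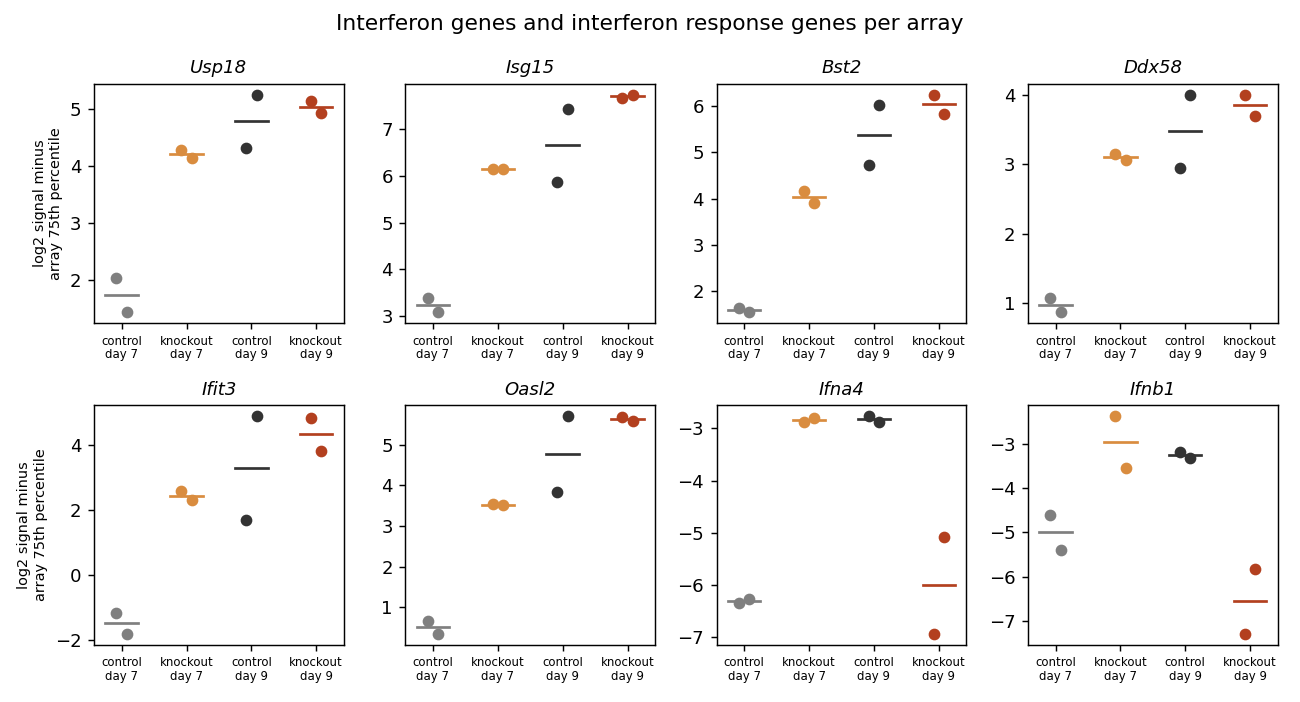
Each panel shows 1 interferon response gene or interferon gene, with log2 signal minus the array's 75th percentile on the vertical axis, a point per array for each of the 4 groups on the horizontal axis and a line at the group mean (n = 2). Usp18 lies 2.47 higher in knockout than in control cells on day 7 and 3.04 higher on day 9 than on day 7 in control cells.

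Neuronal lists had medians below control on day 7, with no call over all genes except 1 postsynaptic gene. Of 27 synaptic vesicle and release genes, 0 passed by limma (14 lower at an unadjusted p under 0.05) and 12 were lower over the list alone (camera adjusted p = 2.81e-06, adjusted p = 0.348 with an estimated correlation). Among them, the vesicle glycoprotein gene Sv2a stood at -0.72 ± 0.15 (0.0981) and the active zone gene Pclo at -1.02 ± 0.22 (0.102). Of 22 voltage-gated channel genes, 0 passed (11 lower unadjusted) and 8 were lower over the list alone, with a median of -0.67, or -0.36 under normexp (camera adjusted p = 2.81e-06, adjusted p = 0.348 with an estimated correlation). The sodium channel gene Scn8a stood at -0.91 ± 0.17 (0.0918). Of 23 axon cytoskeleton genes, 0 passed (11 lower unadjusted) and 11 were lower over the list alone, with a median of -0.45 (camera adjusted p = 1.04e-05, adjusted p = 0.382 with an estimated correlation), the axonal motor gene Kif1a at -0.66 ± 0.13 (0.0955). Of 15 clustered protocadherins, which give neurons their surface identity, 0 passed (10 lower unadjusted) and 9 were lower over the list alone, with a median of -0.64 (camera adjusted p = 3.35e-05, adjusted p = 0.348 with an estimated correlation). Pcdha9 stood at -0.96 ± 0.19 (0.0965). Of 22 postsynaptic and adhesion genes, the kinase gene Camk2a fell by 1.44 ± 0.16 (0.0386), and 4 were lower over the list alone (camera adjusted p = 0.00189, adjusted p = 0.348 with an estimated correlation). Of 27 neurotransmitter receptor genes, 0 passed (9 lower unadjusted) and 7 were lower over the list alone (camera adjusted p = 0.000503, adjusted p = 0.348 with an estimated correlation), with the metabotropic glutamate receptor gene Grm5 at -1.33 ± 0.25 (0.0937).

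Of 10 genes of the floor plate, the ventral midline source of Sonic hedgehog, 0 passed on day 7 (7 lower unadjusted) and 6 were lower over the list alone, with a median of -0.60 (camera adjusted p = 7.08e-05, adjusted p = 0.348 with an estimated correlation). Shh itself stood at -0.86 ± 0.13 (0.0712) and the guidance cue gene Slit1 at -0.88 ± 0.14 (0.0747). Of 18 pluripotency genes, 0 passed (10 lower unadjusted) and 9 were lower over the list alone, with a median of -0.90 (camera adjusted p = 7.96e-05, adjusted p = 0.382 with an estimated correlation). The growth factor gene Gdf3 stood at -1.32 ± 0.36 (0.144) and the Nodal co-receptor gene Tdgf1 at -1.22 ± 0.37 (0.167). Of 18 mesoderm, fibroblast and endothelial genes, 0 passed (10 higher and 1 lower unadjusted), and 9 were higher and 1 lower over the list alone, with a median of 0.67, or 0.41 without control day 7 replicate 2 (camera adjusted p = 0.000503, adjusted p = 0.382 with an estimated correlation). The surface glycoprotein gene Thy1 stood at 2.25 ± 0.30 (0.0601) and the collagen-binding proteoglycan gene Lum at 1.42 ± 0.30 (0.0991). Of 28 cell cycle genes, 27 had positive changes with a median of 0.23, 0 passed by limma (4 higher unadjusted) and 0 adjusted over the list alone (camera adjusted p = 1.87e-05, adjusted p = 0.382 with an estimated correlation). The proliferation marker gene Mki67 differed by 0.03 ± 0.14 (0.940).

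Motor neuron identity genes gave 0 calls over 20 measured members on day 7 (3 higher and 6 lower unadjusted), and 1 higher and 4 lower over the list alone, with a median of -0.41 (camera adjusted p = 0.0429, adjusted p = 0.554 with an estimated correlation). The motor neuron factor genes Isl1 and Lhx3 stood at -0.71 ± 0.47 (0.467) and 0.92 ± 0.16 (0.0811), the acetylcholine synthesis gene Chat at -0.84 ± 0.24 (0.147) and the progenitor factor gene Olig2 at 0.94 ± 0.37 (0.248). On day 7, 18 of 39 lists passed at the preset correlation, 8 up and 10 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.348. The 53 calls became 24 without control day 7 replicate 1, 0 without control day 7 replicate 2, 7 without knockout day 7 replicate 1 and 17 without knockout day 7 replicate 2. They became 125 without either replicate of control day 9 and 7 without either replicate of knockout day 9, arrays that enter only through the pooled spread.

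Knockout and control cells were next compared on day 9, the later sampling. Fewer transcripts of neuronal machinery were found in knockout cells: 10 of 27 synaptic vesicle genes and 12 of 23 axon cytoskeleton genes fell, with medians of -0.89 and -0.77. The motor neuron progenitor genes Olig2 (2.92 ± 0.37, adjusted p = 0.0197) and Olig1 (2.39 ± 0.37, 0.0271) rose. Of the imprinted genes, Meg3 stood at 2.24 ± 0.22 (0.0137), H19 at 2.27 ± 0.21 (0.0122) and Grb10 at -3.02 ± 0.28 (0.0135). In all 1347 genes passed, 371 higher and 976 lower, and 6328 had an unadjusted p under 0.05. The share of higher calls, 27.5%, was 37.0% of 1100 calls after quantile normalization and 65.1% of 1750 after a median shift. So the excess of falls was not fixed. Of calls with a symbol, 303 were higher and 590 lower. Of the higher, 115 lay on chromosome 11, and no list or member result allows for this.

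Among the largest rises on day 9 stood genes with both control arrays below background, for which only a bound holds. The pattern recognition receptor gene Tlr12 was at least 3.60-fold higher (adjusted p = 0.00601) and the fatty acid carrier gene Fabp4 at least 3.07-fold (0.0264). The membrane protein gene Cyyr1 was at least 2.55-fold higher (0.0341) and the interneuron progenitor factor gene Dbx1 at least 2.52-fold (0.0229). Mr1, which presents vitamin metabolites to T cells, was at least 1.81-fold higher (0.0157), the fatty acid transporter gene Slc27a6 at least 1.56-fold (0.0197) and the secreted chemokine-like gene Tafa4 at least 1.5-fold (0.0197). Thy1 rose by 2.57 ± 0.30 (0.0177).

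Among the largest falls on day 9, only a bound holds where both knockout arrays were below background. The trophoblast-specific gene Tpbpb was at least 15.1-fold lower (adjusted p = 0.0197), and the placental cathepsins Ctsr and Ctsq at least 9.21-fold (0.0103) and 7.05-fold (0.0480). Ctsj, of the same family, fell by 3.61 ± 0.58 (0.0284), Serpinb9g by 3.59 ± 0.23 (0.00560) and Serpinb9d by 3.78 ± 0.41 (0.0157), with 1 of 2 knockout arrays below background for Serpinb9d. Rasgrf1, an imprinted exchange factor for Ras, was at least 12.1-fold lower (0.00560). Pramel16, of a family active in germ cells, was at least 6.5-fold lower (0.0395). The noncoding transcript 4930563M21Rik was at least 3.05-fold lower (0.0163), and the gene model Gm8300, above background on 1 of 2 control arrays, at least 2.76-fold (0.0335).

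Of the 5 Dlk1-Dio3 genes, 2 rose and 1 fell on day 9, and 2 were higher and 2 lower over the list alone (camera adjusted p = 0.504, adjusted p = 0.739 with an estimated correlation). Mirg rose by 1.86 ± 0.21 (0.0161), and Begain, a postsynaptic density gene beside the cluster, fell by 1.17 ± 0.15 (0.0199). Of the 19 other imprinted genes 2 rose and 3 fell, and 4 were higher and 3 lower over the list alone (camera adjusted p = 0.545, adjusted p = 0.739 with an estimated correlation), with a median of 0.04 and a mean of -0.12. Zim1 fell by 3.11 ± 0.38 (0.0186). Impact, a translation regulator, rose by 0.76 ± 0.12 (0.0275). Of the 3 Y-linked genes, Ddx3y rose by 1.18 ± 0.14 (0.0181) and Eif2s3y by 0.96 ± 0.13 (0.0203), Uty stood at 1.14 ± 0.33 (0.0982) with 1 of 2 control arrays below background, and 3 were higher over the list alone.

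Of the 27 synaptic vesicle genes, 0 were higher and 10 lower on day 9, and 22 were lower over the list alone (camera adjusted p = 4.48e-11, adjusted p = 0.273 with an estimated correlation). The active zone scaffold gene Bsn fell by 1.18 ± 0.12 (0.0146), Sv2a by 1.16 ± 0.15 (0.0197), the calcium sensor gene Syt4 by 1.56 ± 0.21 (0.0209) and the vesicle membrane gene Syp by 0.96 ± 0.15 (0.0263). Of the 23 axon cytoskeleton genes, 0 were higher and 12 lower, and 19 were lower over the list alone (camera adjusted p = 6.52e-11, adjusted p = 0.382 with an estimated correlation). The kinesin genes Kif5a and Kif1a fell by 1.25 ± 0.14 (0.0161) and 1.18 ± 0.13 (0.0162), and Gap43, a growth cone gene, by 1.16 ± 0.15 (0.0201). Of 15 protocadherins, 7 fell and 13 were lower over the list alone, with a median of -1.02 (camera adjusted p = 2.52e-07, adjusted p = 0.382 with an estimated correlation). Pcdha8 fell by 1.25 ± 0.14 (0.0157) and Pcdha9 by 1.20 ± 0.19 (0.0284). Of 22 channel genes, 6 fell, and 1 was higher and 9 lower over the list alone, with a median of -0.66 (camera adjusted p = 5.89e-05, adjusted p = 0.382 with an estimated correlation). The potassium channel genes Kcnma1 and Kcna1 fell by 1.30 ± 0.20 (0.0271) and 1.78 ± 0.33 (0.0361). Of 27 receptor genes, 1 rose and 3 fell, among them the NMDA receptor subunit gene Grin1 at -1.48 ± 0.16 (0.0153), and 1 was higher and 9 lower over the list alone (camera adjusted p = 0.000723, adjusted p = 0.382 with an estimated correlation).

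**Figure D4:**
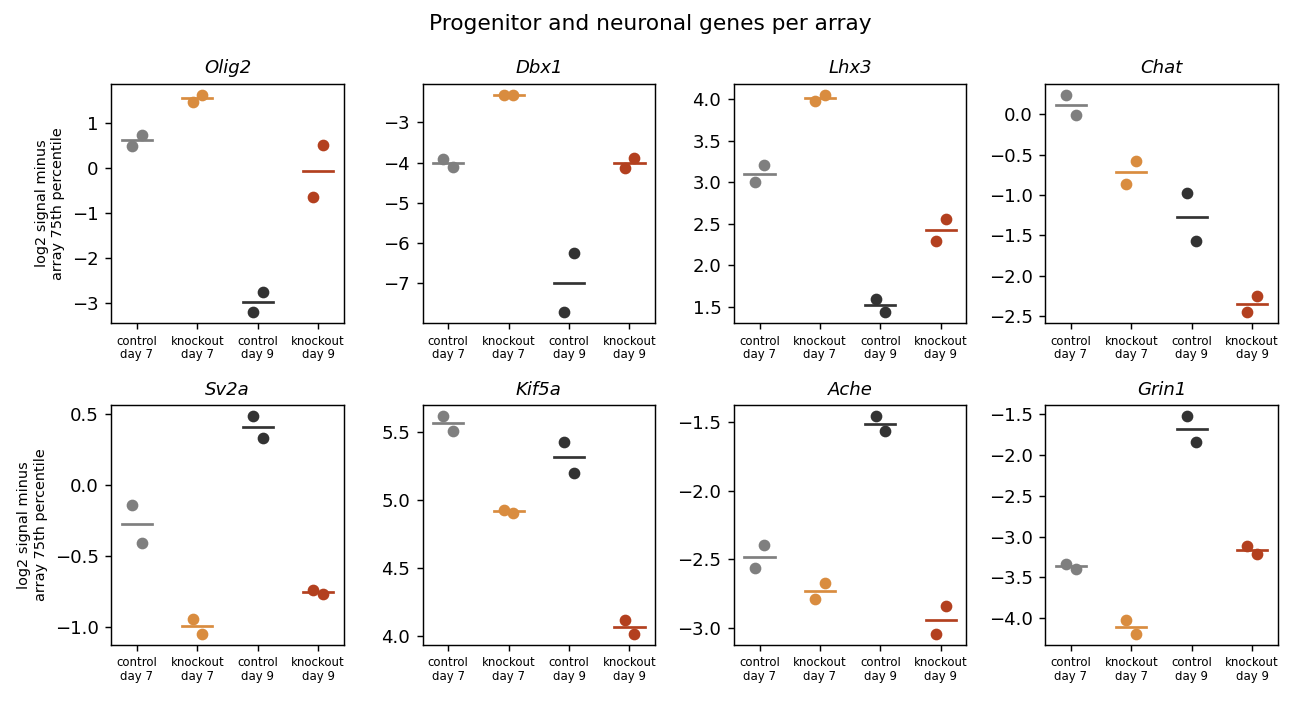
Each panel shows 1 progenitor or neuronal gene, with log2 signal minus the array's 75th percentile on the vertical axis, a point per array for each of the 4 groups on the horizontal axis and a line at the group mean (n = 2). On day 9 Olig2 lies 2.92 higher in knockout than in control cells, and Sv2a, Kif5a and Grin1 lie lower, at -1.16, -1.25 and -1.48.

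Motor neuron identity genes moved both ways on day 9: of 20 measured, 2 rose and 7 fell, and 3 were higher and 9 lower over the list alone, with a median of -0.69, or -0.25 and -1.34 without control day 9 replicate 1 and 2 (camera adjusted p = 0.0275, adjusted p = 0.542 with an estimated correlation). The acetylcholine esterase gene Ache fell by 1.43 ± 0.14 (0.0142), the microtubule regulator gene Stmn2 by 1.20 ± 0.13 (0.0162) and Onecut2, a factor that maintains Isl1, by 1.35 ± 0.16 (0.0184). Lhx3 rose by 0.91 ± 0.16 (0.0325). Chat stood at -1.08 ± 0.24 (0.0519) and Isl1 at -0.59 ± 0.47 (0.472). Of 25 spinal progenitor genes, 8 rose and 1 fell, and 11 were higher and 2 lower over the list alone, with a median of 0.35, or 0.13 without knockout replicate 2 of day 9 (camera adjusted p = 0.00286, adjusted p = 0.417 with an estimated correlation). Besides Olig2 and Olig1 these included the Notch ligand gene Dll3 (0.93 ± 0.16, 0.0333). Of 13 astrocyte genes, 1 rose, the glial switch gene Sox9 (1.53 ± 0.32, 0.0478), also the count adjusted over the list alone, with a median of 0.53, or 0.30 and 0.82 without control replicate 1 and 2 of day 9 (camera adjusted p = 0.0185, adjusted p = 0.383 with an estimated correlation). Gpr17, a receptor of oligodendrocyte precursors, rose by 1.58 ± 0.23 (0.0238). Of 18 interneuron genes, 3 fell, and 1 was higher and 5 lower over the list alone, with a median of -0.38 (camera adjusted p = 0.00941, adjusted p = 0.383 with an estimated correlation). Of these Dmrt3, of commissural cells, fell by 2.00 ± 0.25 (0.0190) and Gad2, which makes GABA, by 1.07 ± 0.17 (0.0275).

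Of 18 pluripotency genes, 3 fell on day 9 and 9 were lower over the list alone, with a median of -1.06 (camera adjusted p = 8.78e-05, adjusted p = 0.383 with an estimated correlation). The RNA-binding gene Lin28a fell by 1.18 ± 0.18 (0.0244), Dppa5a by 1.82 ± 0.29 (0.0275) and the zinc finger gene Sall4 by 0.90 ± 0.16 (0.0346). Of 14 retinoic acid response genes, 3 rose and 4 were higher over the list alone, with a median of 0.38 (camera adjusted p = 0.0118, adjusted p = 0.383 with an estimated correlation). These included the retinol receptor gene Stra6 (1.67 ± 0.17, 0.0143) and the transglutaminase gene Tgm2 (1.02 ± 0.19, 0.0362). Of 18 mesoderm, fibroblast and endothelial genes, 3 rose, among them the collagen gene Col1a1 (1.51 ± 0.30, 0.0418) and the periostin gene Postn (1.51 ± 0.31, 0.0441). Over the list alone 5 were higher and 1 lower (camera adjusted p = 0.148, adjusted p = 0.748 with an estimated correlation). The median of 0.09 ran from -0.05 to 0.23 with a day 9 array left out. Of 22 extracellular matrix genes, 1 rose, Col1a1 again, and 2 were higher over the list alone (camera adjusted p = 0.0118, adjusted p = 0.383 with an estimated correlation). All 28 cell cycle genes had positive changes with a median of 0.34, 0 passed by limma (12 higher unadjusted) and 0 adjusted over the list alone (camera adjusted p = 2.52e-07, adjusted p = 0.383 with an estimated correlation). The mitotic genes Top2a (0.67 ± 0.15, 0.0573), Kif20a (0.56 ± 0.14, 0.0652) and Mki67 (0.25 ± 0.14, 0.324) did not pass.

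Of the 16 interferon response genes, 15 lay above control on day 9 with a median of 0.84, or -0.12 without control replicate 1 and 1.81 (3 calls) without control replicate 2. With all arrays 0 passed by limma (0 at an unadjusted p under 0.05) and 0 adjusted over the list alone (camera adjusted p = 0.0152, adjusted p = 0.748 with an estimated correlation). Isg15 stood at 1.05 ± 0.46 (0.209) and the RNA-sensing synthetase gene Oas1a at 1.26 ± 0.58 (0.232). The interferon genes, chosen after their values were seen, were lower in knockout cells: Ifna4 fell by 3.19 ± 0.53 (0.0303), with 1 of 2 knockout arrays below background, and Ifnb1 was at least 5.93-fold lower (0.0330). On day 9, 17 of 39 lists passed at the preset correlation, 7 up and 10 down, and 0 with an estimated correlation (smallest adjusted p 0.273). The 1347 calls became 63 without control day 9 replicate 1, 530 without control day 9 replicate 2, 86 without knockout day 9 replicate 1, 7 without knockout day 9 replicate 2, and 809 and 616 without either replicate of control and knockout day 7. In the same order, in tests added after the data were seen, the synaptic vesicle list had 0, 5, 2 and 0 lower calls (14, 20, 20 and 18 lower and 0, 1, 0 and 0 higher over the list alone). The axon cytoskeleton list had 0, 7, 0 and 0 lower calls (13, 17, 12 and 15), the motor neuron identity list 0, 8, 1 and 0, the interneuron list 0 each time, the protocadherin list 0, 1, 0 and 0 (11, 12, 12 and 10) and the progenitor list 1, 4, 1 and 0 higher calls (9, 11, 9 and 9 higher and 1, 2, 1 and 1 lower).

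The comparison of day 9 with day 7 in control cells asked how transcripts changed with time in culture without the knockout. Interferon response genes rose in 14 of 16 measured members, with a median of 3.29. Floor plate genes rose in 8 of 10, with Shh at 1.64 ± 0.13 (adjusted p = 0.00652), while Nkx2-9, of the same list, fell by 3.47 ± 0.25 (0.00629). Progenitor genes that fell included Olig2 (-3.61 ± 0.37, 0.00843) and the proneural gene Neurog2 (-2.66 ± 0.30, 0.0101). Of all genes, 1817 passed, 1013 higher and 804 lower, and 6420 had an unadjusted p under 0.05. The share of higher calls, 55.8%, was 67.8% after a median shift and 69.6% under normexp.

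Among the largest rises in control cells were the interferon-induced genes Ifi44 (6.01 ± 0.95, adjusted p = 0.0213), with 1 of 2 arrays of day 7 below background, the nucleic acid sensor gene Zbp1 (4.86 ± 0.74, 0.0197), and Ifit3 and Ifit3b (4.78 ± 0.96 and 4.49 ± 0.95, 0.0382 and 0.0425), which bind foreign RNA. Ifi27l2a, a mitochondrial protein gene of this response, rose by 4.64 ± 0.51 (0.00910). Over the interferon list, 14 rose and 16 were higher over the list alone (camera adjusted p = 2.76e-16, adjusted p = 0.398 with an estimated correlation). Bst2 rose by 3.79 ± 0.40 (0.00884), Usp18 by 3.04 ± 0.33 (0.00897), the synthetase-like gene Oasl2 by 4.26 ± 0.54 (0.0126) and Ddx58 by 2.50 ± 0.33 (0.0150). Ifna4, chosen after its value was seen, was at least 6.64-fold higher (0.0196), and Ifnb1 stood at 1.75 ± 0.57 (0.119), with 1 of 2 arrays of day 7 below background.

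Other large rises in control cells were of genes dim on day 7. The lipid regulator gene Ccdc3 was at least 15.6-fold higher (adjusted p = 0.00473), Ecrg4, a secreted neuropeptide of choroid plexus, at least 12.1-fold (0.00737) and the galanin receptor gene Galr1 at least 8.15-fold (0.00706). The matrix genes Ogn, with 1 of 2 arrays of day 7 below background, and Col8a2 rose by 4.44 ± 0.67 (0.0192) and 4.26 ± 0.23 (0.00374). Falls included the axonal adhesion gene Cntn2 (-3.39 ± 0.41, 0.0113), the secreted phosphoprotein gene Spp2 (-3.37 ± 0.26, 0.00629) and the tight junction gene Cldn3 (-3.19 ± 0.28, 0.00707). The protease inhibitor gene Wfdc6b fell by 3.76 ± 0.77 (0.0403) and the retroviral gene Erv3 by 3.30 ± 0.47 (0.0170), each with 1 of 2 arrays of day 9 below background. The hexokinase gene Hk3 was at least 5.04-fold lower (0.0384), the defensin gene Defb36 at least 2.79-fold (0.0293) and the lipid hydrolase gene Adtrp at least 2.01-fold (0.0203).

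Of the 10 floor plate genes, 8 rose and 1 fell in control cells, with the same counts adjusted over the list alone and a median of 1.71 (camera adjusted p = 4.65e-08, adjusted p = 0.345 with an estimated correlation). The heparan sulphate editor gene Sulf1 rose by 1.97 ± 0.15 (0.00629). Of 25 progenitor genes, 8 fell, and 1 was higher and 14 lower over the list alone, with a median of -0.60 (camera adjusted p = 0.00109, adjusted p = 0.466 with an estimated correlation). Olig1 fell by 3.11 ± 0.37 (0.0110), and Dbx1 was at least 2.50-fold lower (0.0183). Of 20 motor neuron identity genes, 2 rose and 8 fell, and 2 were higher and 12 lower over the list alone, with a median of -0.91 (camera adjusted p = 0.00133, adjusted p = 0.466 with an estimated correlation). Lhx3 fell by 1.59 ± 0.16 (0.00815), Chat by 1.39 ± 0.24 (0.0252) and the vesicle transporter gene Slc10a4 by 1.86 ± 0.25 (0.0151), while Ache rose by 0.97 ± 0.14 (0.0190). Isl1 stood at -1.58 ± 0.47 (0.0954) and Mki67 at -0.16 ± 0.14 (0.522).

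Of 27 synaptic vesicle genes, 4 rose with time in control cells, including the synapsin gene Syn2 (1.82 ± 0.17, 0.00718) and the fusion gene Vamp1 (1.15 ± 0.18, 0.0202), and 6 were higher and 2 lower over the list alone, with a median of 0.29, or 0.15 without control day 9 replicate 1 (camera adjusted p = 0.00213, adjusted p = 0.398 with an estimated correlation). Of 27 receptor genes, 6 rose and 3 fell, and 7 were higher and 4 lower over the list alone, with a median of 0.37 (camera adjusted p = 0.00242, adjusted p = 0.398 with an estimated correlation). Grin1 rose by 1.68 ± 0.16 (0.00729), and the nicotinic receptor gene Chrna3 fell by 1.32 ± 0.13 (0.00819). Of 23 axon cytoskeleton genes, 2 fell, the neurofilament genes Nefm (-2.06 ± 0.24, 0.0109) and Nefl (-1.10 ± 0.21, 0.0321), and 2 were lower over the list alone (camera adjusted p = 0.151, adjusted p = 0.830 with an estimated correlation). Of 14 retinoic acid response genes, 1 rose and 3 fell, and 1 was higher and 6 lower over the list alone, with a median of -0.47 (camera adjusted p = 0.132, adjusted p = 0.552 with an estimated correlation). The carriers of retinoic acid Crabp2 (-2.91 ± 0.31, 0.00895) and Crabp1 (-1.44 ± 0.22, 0.0196) fell. The retinal reductase gene Dhrs3 rose by 1.79 ± 0.29 (0.0216).

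Of 13 astrocyte genes, 2 rose with time in control cells and 6 were higher over the list alone, with a median of 0.72, or 0.26 without control day 9 replicate 2 (camera adjusted p = 0.000124, adjusted p = 0.398 with an estimated correlation). They were the folate enzyme gene Aldh1l1 (2.22 ± 0.44, 0.0373) and the matrix gene Tnc, at least 1.81-fold higher (0.0159). Of 22 extracellular matrix genes, 5 rose and 7 were higher over the list alone, with a median of 0.60 (camera adjusted p = 3.38e-07, adjusted p = 0.345 with an estimated correlation), Col6a1 by 2.13 ± 0.20 (0.00718). Of 18 mesoderm, fibroblast and endothelial genes, 6 rose and 8 were higher over the list alone, with a median of 0.65 (camera adjusted p = 1.91e-05, adjusted p = 0.440 with an estimated correlation), Postn by 2.13 ± 0.31 (0.0175), the proteoglycan gene Dcn by 2.14 ± 0.30 (0.0170) and the smooth muscle gene Tagln by 1.88 ± 0.20 (0.00897). For this contrast 16 of 39 lists passed at the preset correlation, 12 up and 4 down, and 0 with an estimated correlation (smallest adjusted p 0.345). The 1817 calls became 719 without control day 7 replicate 1, 8 without control day 7 replicate 2 and 180 without control day 9 replicate 2. They became 1066 without either replicate of knockout day 7 and 876 without either replicate of knockout day 9.

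The comparison of day 9 with day 7 in knockout cells asked the same of cells without Litchi. Floor plate genes rose in 9 of 10 members, with a median of 2.00 and Shh at 2.14 ± 0.13 (adjusted p = 0.00397). Astrocyte genes rose in 5 of 13, with Aldh1l1 at 3.78 ± 0.44 (0.00771). Axon cytoskeleton genes fell in 8 of 23, with Nefm at -2.78 ± 0.24 (0.00520). Of all genes, 2045 passed, 1021 higher and 1024 lower, and 6413 had an unadjusted p under 0.05. The share of higher calls, 49.9%, was 66.0% after a median shift.

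Among the largest rises in knockout cells, Ecrg4 was at least 19-fold higher (adjusted p = 0.00500). The axonemal dynein gene Dnali1 rose by 4.23 ± 0.42 (0.00612), with 1 of 2 arrays of day 7 below background. Another axonemal gene, Vwa3a, was at least 8.09-fold higher (0.00786). The radial spoke gene Dnajb13 was at least 6.36-fold higher (0.0345), Galr1 at least 6.83-fold (0.00538) and the endothelial proteoglycan gene Esm1 at least 5.21-fold (0.0127). The zinc transporter gene Slc39a12, an astrocyte transcript, rose by 4.96 ± 0.70 (0.0119), with 1 of 2 arrays of day 7 below background. The secreted synaptic gene Lgi3 rose by 3.83 ± 0.43 (0.00727) and Col8a2 by 3.81 ± 0.23 (0.00397). The interferon gene Ifnb1 was at least 7.26-fold lower (0.0167). Genes dim on day 9 and lower by a bound were Defb36 (6.17-fold, 0.0178), the apoptosis facilitator gene Bcl2l14 (5.79-fold, 0.00982), the sperm head gene Cylc1 (5.23-fold, 0.0223), the AMP deaminase gene Ampd1 (4.02-fold, 0.0265) and the carotene oxygenase gene Bco1 (3.25-fold, 0.00171), each at least. Cldn3 fell by 3.65 ± 0.28 and Spp2 by 3.59 ± 0.26 (both 0.00482), and Hk3 by 3.51 ± 0.71 (0.0342) and Adtrp by 3.34 ± 0.50 (0.0138), each of the latter with 1 of 2 arrays of day 9 below background.

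Of the 10 floor plate genes, 9 rose and 1 fell in knockout cells, with the same counts adjusted over the list alone (camera adjusted p = 8.13e-10, adjusted p = 0.327 with an estimated correlation). The floor plate helix-loop-helix gene Ferd3l rose by 2.09 ± 0.19 (0.00535) and Sulf1 by 1.92 ± 0.15 (0.00482). Of 13 astrocyte genes, 5 rose and 10 were higher over the list alone, with a median of 1.11 (camera adjusted p = 2.63e-06, adjusted p = 0.327 with an estimated correlation). Tnc was at least 2.80-fold higher (0.0145), and the growth factor receptor gene Fgfr3 and the stem cell gene Hopx rose by 1.05 ± 0.22 (0.0358) and 1.85 ± 0.39 (0.0394). Of 22 extracellular matrix genes, 4 rose, and 8 were higher and 1 lower over the list alone, with a median of 0.65 (camera adjusted p = 2.95e-07, adjusted p = 0.327 with an estimated correlation). The collagen genes Col6a1 and Col6a2 of that list rose by 2.36 ± 0.20 (0.00482) and 2.51 ± 0.25 (0.00620). Of 18 mesoderm, fibroblast and endothelial genes, 5 rose and 1 fell, and 7 were higher and 1 lower over the list alone, with a median of 0.50, or 0.31 without knockout day 7 replicate 2 (camera adjusted p = 0.000861, adjusted p = 0.549 with an estimated correlation).

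Of 20 motor neuron identity genes, 1 rose and 8 fell in knockout cells, and 1 was higher and 14 lower over the list alone, with a median of -1.02 (camera adjusted p = 8.52e-06, adjusted p = 0.485 with an estimated correlation). The peripherin gene Prph fell by 2.33 ± 0.25 (0.00701), the acetylcholine transporter gene Slc18a3 by 1.89 ± 0.23 (0.00796), Lhx3 by 1.59 ± 0.16 (0.00606), Onecut2 by 1.20 ± 0.16 (0.0108) and Chat by 1.63 ± 0.24 (0.0124). Isl1 stood at -1.47 ± 0.47 (0.112) and Mki67 at 0.06 ± 0.14 (0.828). Of 23 axon cytoskeleton genes, 8 fell and 13 were lower over the list alone, with a median of -0.53 (camera adjusted p = 6.3e-06, adjusted p = 0.549 with an estimated correlation). Nefl fell by 2.04 ± 0.21 (0.00612), Ina, another filament gene, by 1.21 ± 0.17 (0.0117) and Stmn2 by 0.98 ± 0.13 (0.0109). Of 25 progenitor genes, 2 rose and 5 fell, and 2 were higher and 7 lower over the list alone (camera adjusted p = 0.482, adjusted p = 0.835 with an estimated correlation). Olig2 fell by 1.63 ± 0.37 (0.0481), Olig1 by 1.90 ± 0.37 (0.0313) and Neurog2 by 2.12 ± 0.30 (0.0122).

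Of 14 retinoic acid response genes, 2 rose and 4 fell in knockout cells, and 4 were higher and 6 lower over the list alone (camera adjusted p = 0.591, adjusted p = 0.835 with an estimated correlation). Crabp2 fell by 2.59 ± 0.31 (0.00810) and Crabp1 by 1.62 ± 0.22 (0.0104). Of 18 pluripotency genes, 2 fell, Lin28a by 2.14 ± 0.18 (0.00482) and Sall4 by 1.58 ± 0.16 (0.00629), and 1 was higher and 5 lower over the list alone (camera adjusted p = 0.248, adjusted p = 0.835 with an estimated correlation). Of the 16 interferon response genes, 1 rose, Bst2 by 2.01 ± 0.40 (0.0332), and 8 were higher over the list alone, with a median of 1.75 (camera adjusted p = 1.31e-06, adjusted p = 0.549 with an estimated correlation). Oasl2 stood at 2.09 ± 0.54 (0.0655). Here 12 of 39 lists passed at the preset correlation, 9 up and 3 down, and 0 with an estimated correlation (smallest adjusted p 0.327). The 2045 calls became 1118 without knockout day 7 replicate 1, 438 without knockout day 7 replicate 2, 491 without knockout day 9 replicate 1 and 561 without knockout day 9 replicate 2.

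The interaction term asked whether the knockout effect differed between the days. At the level of lists, interferon response genes had the farthest shift, with a median difference between the day 9 and day 7 effects of -1.82 (-1.13 without control day 9 replicate 2) and 0 of 16 members above 0. Axon cytoskeleton genes (median -0.37, 0 of 23 above 0) shifted the same way, and spinal progenitor genes the other way (median 0.54, 21 of 25 above 0), at 0.28 under normexp and 0.23 without knockout day 9 replicate 2. Single genes could rarely be told apart: 1 of 24623 passed, XM_143529, a gene model without a symbol (-3.01 ± 0.19, adjusted p = 0.0494), and 1479 had an unadjusted p under 0.05. That gene no longer passed under the 4 other scalings, or without either replicate of control day 7, either replicate of control day 9 or knockout day 7 replicate 2, each of which left 0 calls (between 741 and 1667 genes at an unadjusted p under 0.05).

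Of 39 lists, 7 passed for the interaction at the preset correlation, 2 up and 5 down, and 0 with an estimated correlation, where each of these 7 had an adjusted p of 0.786. The camera adjusted p was 1.36e-10 for interferon response genes (0 calls by limma, 8 lower at an unadjusted p under 0.05, and 1 lower over the list alone). It was 9.02e-07 for axon cytoskeleton genes (0 calls, 5 lower unadjusted, 0 adjusted over the list alone). Synaptic vesicle genes (median -0.40, 0 calls, 5 lower unadjusted, 0 adjusted over the list alone) gave 1.23e-05. Spinal progenitor genes (0 calls, 7 higher unadjusted, 0 adjusted over the list alone) gave 4.83e-05 and floor plate genes (median 0.51, 0 calls, 4 higher unadjusted, 0 adjusted over the list alone) 0.000148. Protocadherins (median -0.28, or -0.43 and -0.16 without knockout day 7 replicate 2 and 1, 0 calls, 2 lower unadjusted, 0 adjusted over the list alone) gave 0.00888 and skeletal muscle genes (median -0.66, or -1.11 and -0.05 without control day 7 replicate 1 and 2, 0 calls, 2 lower unadjusted, 1 lower over the list alone) 0.0479. Among single genes, the interferon genes Ifnab, Ifna5 and Ifna13 stood at -2.23 ± 0.23 (adjusted p = 0.248), -2.71 ± 0.29 (0.248) and -3.15 ± 0.36 (0.281), with 1 array each of control day 7 and knockout day 9 below background for Ifna13. These close copies can share targets. Of the response genes, Usp18 stood at -2.22 ± 0.47 (0.712), Ddx58 at -1.75 ± 0.47 (0.751) and Bst2 at -1.78 ± 0.57 (0.805).

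Genes with positive differences between the effects, none of which passed, included Gpr17 (2.42 ± 0.33, adjusted p = 0.319), the NMDA receptor subunit gene Grin2c (1.93 ± 0.27, 0.330), the sialyltransferase gene St8sia5 (1.48 ± 0.20, 0.319) and the GABA receptor gene Gabrg1 (1.25 ± 0.21, 0.555). Olig2 stood at 1.99 ± 0.53 (0.750), Isl1 at 0.12 ± 0.67 (0.992), Lhx3 at -0.0049 ± 0.22 (0.999), Chat at -0.24 ± 0.33 (0.938) and Mki67 at 0.22 ± 0.20 (0.910). In simulated data this term called 1% of 2-fold and 60% of 4-fold changes, so most 2-fold changes would go unseen.

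The mean of both days sets 4 knockout arrays against 4 control arrays and asked which genes differed on average over the days. Of the imprinted genes, Meg3 stood at 2.25 ± 0.15 (adjusted p = 0.00294), H19 at 2.14 ± 0.15 (0.00294) and Grb10 at -3.45 ± 0.20 (0.00168). Serpinb9g was lower, at -3.49 ± 0.16 (0.00116). Synaptic vesicle genes fell in 17 of 27 members with a median of -0.72, and interferon response genes rose in 10 of 16 with a median of 1.69. Y-linked genes rose in 3 of 3. Of all genes, 3652 passed, 1351 higher and 2301 lower, and 8287 had an unadjusted p under 0.05. The share of higher calls, 37.0%, was 48.2% of 3396 calls after quantile normalization and 71.6% of 4604 calls after a median shift, so the excess of falls was not fixed.

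The largest rises were of the neural crest factor gene Tfap2b (3.12 ± 0.68, adjusted p = 0.0324), with 1 of 2 control arrays below background on each day, the interferon-induced GTPase gene Tgtp2 (2.83 ± 0.57, 0.0262), and Trim30d and Trim30a (2.80 ± 0.61 and 2.75 ± 0.63, 0.0324 and 0.0363), close copies of an immune regulator with 1 control array of day 7 below background. The cartilage gene Cnmd also rose (0.0445), with all control arrays below background. The placental genes Ctsr (0.00258), Tpbpb (0.00699) and Ctsq (0.0253) fell, with all knockout arrays below background.

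Of the 5 Dlk1-Dio3 genes, 2 rose and 2 fell for the mean of both days, and 3 were higher and 2 lower over the list alone (median 0.59, camera adjusted p = 0.324, adjusted p = 0.484 with an estimated correlation). Mirg rose by 1.55 ± 0.15 (0.00618), and Dio3 and Begain fell by 1.47 ± 0.24 (0.0172) and 0.89 ± 0.11 (0.00995), with 1 knockout array of day 9 below background for Dio3. Of 19 other imprinted genes, 5 rose and 4 fell, with the same counts adjusted over the list alone, a median of 0.21 and a mean of -0.13 (camera adjusted p = 0.272, adjusted p = 0.464 with an estimated correlation). Cdkn1c fell by 1.78 ± 0.17 (0.00618) and Zim1 by 2.63 ± 0.27 (0.00696). The Y-linked genes Ddx3y, Eif2s3y and Uty rose by 1.03 ± 0.10 (0.00620), 0.91 ± 0.09 (0.00674) and 1.13 ± 0.24 (0.0290), and 3 were higher over the list alone.

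Of the 27 synaptic vesicle genes, 17 fell and 22 were lower over the list alone for the mean of both days (camera adjusted p = 2.72e-09, adjusted p = 0.318 with an estimated correlation), Sv2a by 0.94 ± 0.10 (0.00779) and Bsn by 0.86 ± 0.09 (0.00684). Of 23 axon cytoskeleton genes, 16 fell and 19 were lower over the list alone, with a median of -0.63 (camera adjusted p = 8.8e-09, adjusted p = 0.352 with an estimated correlation), Kif1a by 0.92 ± 0.09 (0.00696). Of 22 channel genes, 13 fell and 16 were lower over the list alone, with a median of -0.58 (camera adjusted p = 1.7e-06, adjusted p = 0.318 with an estimated correlation), Kcnma1 by 1.12 ± 0.14 (0.0112). Of 15 protocadherins, 11 fell and 12 were lower over the list alone, with a median of -0.82 (camera adjusted p = 9.57e-07, adjusted p = 0.318 with an estimated correlation), Pcdha8 by 0.94 ± 0.10 (0.00696). Of 20 motor neuron identity genes, 2 rose and 8 fell, and 4 were higher and 11 lower over the list alone, with a median of -0.74, or -0.47 without control day 9 replicate 1 (camera adjusted p = 0.0280, adjusted p = 0.484 with an estimated correlation). Lhx3 rose by 0.91 ± 0.11 (0.00995), Chat fell by 0.96 ± 0.17 (0.0196) and Isl1 stood at -0.65 ± 0.33 (0.223). Of 25 progenitor genes, 8 rose and 2 fell, and 9 were higher and 4 lower over the list alone, with a median of 0.15, or -0.01 and 0.30 without knockout day 9 replicate 2 and 1 (camera adjusted p = 0.0469, adjusted p = 0.509 with an estimated correlation), Olig2 rising by 1.93 ± 0.26 (0.0129).

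Of 16 interferon response genes, 10 rose and 15 were higher over the list alone for the mean of both days (camera adjusted p = 1.18e-08, adjusted p = 0.401 with an estimated correlation), Isg15 by 1.98 ± 0.32 (0.0176) and Usp18 by 1.36 ± 0.24 (0.0197). Of 28 cell cycle genes, 5 rose and 9 were higher over the list alone, with a median of 0.28 (camera adjusted p = 7.77e-08, adjusted p = 0.355 with an estimated correlation), Top2a by 0.60 ± 0.11 (0.0212) and Kif20a by 0.45 ± 0.10 (0.0308), while Mki67 stood at 0.14 ± 0.10 (0.381). Of 18 pluripotency genes, 10 fell and 13 were lower over the list alone, with a median of -0.87 (camera adjusted p = 2.27e-05, adjusted p = 0.401 with an estimated correlation), Dppa5a by 1.35 ± 0.20 (0.0153) and Lin28a by 0.77 ± 0.12 (0.0172), as did Gdf3 (-1.50 ± 0.26, 0.0187). Of 18 mesoderm, fibroblast and endothelial genes, 7 rose and 1 fell, and 8 were higher and 3 lower over the list alone, with a median of 0.36 (camera adjusted p = 0.0156, adjusted p = 0.484 with an estimated correlation). Thy1 rose by 2.41 ± 0.21 (0.00530), Col1a1 by 1.42 ± 0.21 (0.0152) and Lum by 1.36 ± 0.21 (0.0160). Here 22 of 39 lists passed at the preset correlation, 11 up and 11 down, and 0 with an estimated correlation (smallest adjusted p 0.318).

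A split of the mean of both days by chromosome, chosen after the calls were seen, gave chromosome 11 a median change of 0.34 over 1250 genes, with 0.29 on day 7 and 0.38 on day 9. On that chromosome 376 genes rose and 30 fell, out of 1100 that rose on all chromosomes (Fisher's exact test of the rises, two-sided, p = 9.48e-147, a value that treats genes as independent), and 77.7% of its genes had positive changes against 51.5% elsewhere. The other autosomes and the X chromosome had medians between -0.01 and 0.05, and the Y chromosome (6 genes) 0.43. On single arrays, chromosome 11 lay between 0.14 and 0.19 above the other genes in knockout cells and between -0.17 and -0.14 in control cells, each relative to the gene's mean over the 8 arrays. The 3652 calls became 1888 without control day 7 replicate 1, 1700 without control day 7 replicate 2, 1298 without knockout day 7 replicate 1 and 1248 without knockout day 7 replicate 2. They became 1189 without control day 9 replicate 1, 1006 without knockout day 9 replicate 1 and 450 without knockout day 9 replicate 2.

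**Figure D5:**
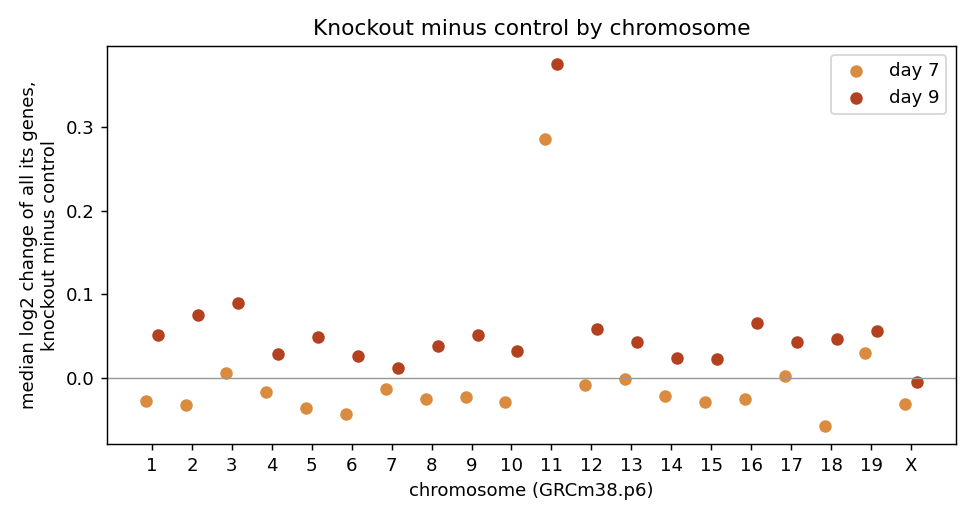
The vertical axis gives the median log2 change, knockout minus control, over all genes of each autosome and of the X chromosome (horizontal axis), with a point for day 7 and a point for day 9. Chromosome 11 lies at 0.29 and 0.38, and no other chromosome shown lies above 0.09.

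Across all genes, which are not independent replicates, the knockout effects of day 7 and day 9, which share no array, correlated at a Pearson r of 0.60 and a Spearman rho of 0.62, and 73.6% of genes had the same sign. Genes called on both days numbered 20 higher, 24 lower and 1 in opposite directions, against 0.36 higher and 1.15 lower for independent sets. Of the 53 genes called on day 7, 51 had the same sign on day 9, and of the 1347 called on day 9, 1274 had the same sign on day 7. The day effects in control and in knockout cells correlated at r = 0.71 and rho = 0.61, with 74.2% of genes of the same sign. Both genotypes shared 618 higher and 402 lower calls, against 42.0 and 33.4 for independent sets, and 7 were opposite.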

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

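The tests of scaling, of single cultures and of an earlier response for the interferon genes, and those of scaling and of the share of motor neurons for the neuronal genes and the counts without single day 9 arrays, were chosen only after the results were seen. 8 results passed a test of the difference between the knockout effects of day 9 and day 7: limma's interaction term for 1 gene and camera at the preset correlation for 7 lists. The gene model XM_143529 had a difference of -3.01 ± 0.19 (log2). The list medians of the difference were -1.82 for interferon response genes, 0.54 for spinal progenitor genes, 0.51 for floor plate and V3 genes, -0.66 for skeletal muscle genes, -0.40 for synaptic vesicle and release genes, -0.37 for axon cytoskeleton genes and -0.28 for clustered protocadherin genes. With an estimated correlation none of these lists passed (adjusted p = 0.786 for each). Groups of 2 arrays are too small for a test of single arrays out of place.

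Interferon response genes lay 2.46 above control in knockout cells on day 7, while on day 9 they lay 0.84 above it (-0.12 without control replicate 1 and 1.81 without control replicate 2) and the interferon genes Ifna4 and Ifnb1 were lower. The list median on day 7 stayed between 2.39 and 2.59 under 4 other scalings, which argues against background of the arrays as the cause. These scalings moved the day 7 median of all genes by at most 0.13, too little to test scaling for a list this far from 0. A response that starts by day 7 in the knockout and by day 9 in the control stays open: the median difference between the effects lay between -2.53 and -1.13 with each array left out, which restates the pattern. Differences between single cultures, whatever their genotype, cannot be told apart from other causes with 2 arrays per group, because the 2 arrays of control day 9 already differed by 1.65 in the list median. An effect of the loss of Litchi on interferon genes stays open, untested.

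On day 9, 10 of 27 synaptic vesicle genes fell in the knockout (median -0.89) and 8 of 25 progenitor genes rose and 1 fell (median 0.35, or 0.13 without knockout replicate 2), with adjusted p of 0.273 and 0.417 with an estimated correlation. Scaling or background is argued against by the synaptic vesicle median, which stayed between -0.93 and -0.68 under 4 other scalings. Progenitor and interneuron genes did not rise alike: the gap between their medians rose by at least 0.67 from each control to each knockout array. Within a group it differed by at most 0.25. The lists had been seen to part, so a lower share of motor neurons alone stays open. A delay along the course from day 7 to day 9 may contribute but cannot be told apart from other causes: across genes, the knockout effect on day 9 and the control day effect, computed from arrays not shared, correlated at 0.26 one way and -0.22 the other. The calls depend on each day 9 array, since the synaptic vesicle list had between 0 and 5 calls with one of them left out, though its median stayed between -1.07 and -0.78, and an effect of the loss of Litchi stays open, untested.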

How the results depend on the processing

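The crossed replicate block and the list counts and medians without single arrays were chosen only after the results were seen, and every other alternative was fixed before the data were examined. All named genes that passed kept their direction under every alternative run. Under quantile normalization, a median shift and the deposited values together, 18 of 22 named calls held on day 7, 53 of 59 on day 9, 48 of 49 for time in control cells, 43 of 45 for time in knockout cells and 38 of 38 for the mean of both days. Under normexp 11 of 22, 32 of 59, 35 of 49, 31 of 45 and 33 of 38 held. With each array left out in turn the calls that always held numbered 0, 0, 1, 21 and 21. Over 5112 comparisons of 276 named values with an alternative, 4024 stayed on their side of the threshold, 1015 were weaker, 59 stronger and 14 reversed. Under normexp the calls were 21 on day 7 (against 53), 306 on day 9 (1347), 694 for time in control cells (1817), 889 for time in knockout cells (2045) and 1682 for the mean of both days (3652), and 16 lists passed for the interaction (7). Without a filter on dim probes they were 0 (3994 at an unadjusted p under 0.05), 1, 75, 480 and 220, and the correlation of the day effects across genes was 0.51 (0.71). For this alternative 37256 genes were tested, many at background. At an adjusted p under 0.10 the calls were 627, 3107, 3588, 3713 and 6355, and with a 2-fold minimum 809 on day 9, 1105 and 1363 for time in control and knockout cells and 878 for the mean of both days, by construction. On day 7, a trend with robust moderation gave 302 calls, probes above background on all 8 arrays 184 and every probe on its own 82. Fits of only the 4 arrays of a comparison, with fewer degrees of freedom, gave 0 on day 7 (3856 at an unadjusted p under 0.05), 52 on day 9 and 182 for time in control cells. The numbers of the titles were not taken to pair the arrays: deviations from group means correlated across genes at r from 0.25 to 0.46 among 3 groups but from -0.25 to 0.04 with knockout day 9. With a replicate block the calls were 102 on day 7 and 2030 on day 9, and 7 of the 276 named values were weaker, 3 stronger and 0 reversed. A crossed replicate block, with the numbers of the day 9 knockout arrays exchanged, gave 2598 on day 9. The 1 call of the interaction became 0 under quantile normalization, the median shift, normexp, the deposited values, no filter, the stricter filter, the floor, every probe on its own, the replicate block and the trend with robust moderation, with between 741 and 2051 genes at an unadjusted p under 0.05. With an estimated correlation 0 lists passed in each of the 6 contrasts. Leaving out 1 array in turn, where the lone array of a group is assumed to vary like the others, gave 0 to 125 calls on day 7 (0 without control day 7 replicate 2, with 3765 at an unadjusted p under 0.05), 7 to 809 on day 9, 8 to 1306 and 438 to 1994 for time in control and knockout cells, 0 to 1 for the interaction and 450 to 2716 for the mean of both days. The lists passing for the interaction then ran from 5 to 14, and the correlation of the day effects from 0.64 to 0.73. That of the knockout effects ran from 0.41 to 0.68 over the other alternatives and from 0.46 to 0.65 with an array left out. Reversed values were all of genes that did not pass. Mki67 ran from -0.0844 to 0.14 on day 7 with an array left out (the lowest without control replicate 1, and -0.0313 without knockout replicate 2). Isl1 ran from -1.37 to 0.19 on day 9. In knockout cells over time Mki67 was -0.0186 by the mean of its probes and ran from -0.0037 to 0.12. For the interaction, Lhx3 was 0.0792 after the median shift and 0.0149 under normexp and ran from -0.14 to 0.13, Isl1 ran from -0.66 to 0.90 and Chat from -0.54 to 0.0593.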

Other observations

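The tests of near-identical copies and of the state of the cell line, the position of the imprinted, Y-linked and placental-family genes on the shifted chromosome, the split by chromosome, 3 added gene lists and the overlap of 2 of them were chosen only after the results were seen. Placental gene families were lower in the knockout: of 32 measured, 23 fell for the mean of both days and 0 rose (limma), with a median of -1.95, and of 22 not named elsewhere 13 fell, with a median of -1.63. Of 16 single-copy trophoblast genes, 11 fell, with a median of -1.12, but 8 of the 16 are also in the placental list, and of the other 8, 7 fell, with a median of -0.84. Krt18 stood at 4.86 in control and 3.39 in knockout cells (log2), Gata3 at 2.37 and 1.66 and Krt8 at 1.05 and -0.52, while Gcm1 stood at 7.5 and 6.89 without passing (adjusted p = 0.0549). Keratins are shared with other epithelia, and 2 of the 16 genes (Gata2 and Gata3) are also in the interneuron list.

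For the mean of both days, 13 of 24 imprinted, 3 of 3 Y-linked and 23 of 32 placental-family genes passed, and near-identical copies on 1 probe cannot be told apart from other causes for the imprinted genes, since probe sequences were not searched. Chromosome 11 met the bound of 0.3 for a gain or loss (median 0.339). Direct dosage is argued against, since 2 of the 39 called genes lie there (Grb10 and Hand1) and 0 rose. Effects on genes elsewhere and a gain of Y stay untested. Trophoblast cells in the control cultures cannot be told apart from other causes of the fall of placental families, since the median of all 16 trophoblast genes, -1.12, met the bound of -1 set before, but that of the 8 outside the placental list, a set chosen afterwards, was -0.845. The state of the cell line or clone, apart from the loss of Litchi, may explain the imprinted and Y-linked genes and cannot be told apart from that loss: 0 of 27 passed the test of the difference between the days (limma, with 1 lower in each of the 2 imprinted lists at an unadjusted p under 0.05), which both would give. Imprinted loci are known to vary between embryonic stem cell lines.

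Genes of chromosome 11 were higher in the knockout on both days, with a median of 0.34 for the mean of both days. A difference in copy number that spans the whole chromosome may explain this, as a hypothesis: each of 10 blocks of its genes, in their order along it, had a median between 0.28 and 0.39 (lowest 0.283), above the bound of 0.15 set before. Windows of 50 genes had medians between 0.02 and 0.47 on chromosome 11 and between -0.46 and 0.24 elsewhere. Shifts of whole arrays cancel in the gap to the other genes (0.328 here, at least 0.296 under 4 other scalings), so scaling stays untested. A ratio of the genotypes cannot separate a gain in knockout cells from a loss in control cells, and gains of chromosome 11 are known in mouse embryonic stem cells.

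Pramel16 and Rhox12 fell in the knockout, and a fall of germline genes as a group was tested. It is argued against: the 28 germline genes not named elsewhere had a median of 0.486, with 9 higher and 1 lower for the mean of both days, and all 35 measured had a median of 0.69 (0.81 on day 7 and 0.09 on day 9), with 13 higher and 3 lower.

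Of 35 splits of the arrays into 4 and 4, only that by genotype called as many genes as the real one (1 of 35). It called 3751 genes with the day in the model, and the highest other split, day 7 against day 9, 2657. Mixed splits put the genotype difference into the spread, so chance between cultures cannot be excluded. Nor can it be for gene lists, as 2 of 35 splits passed as many at the preset correlation. The real split gave 19 and the highest other 20, a split that called 0 genes. Of 3056 tested probes named only by a genome position, 378 were called for the mean of both days, 51 of them higher.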
